A study of Mus musculus with 2 samples.

How the data were processed

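RNA from Colon26 primary tumours and from liver metastases was compared on 2 two-colour oligonucleotide arrays. Per the labels, each array held a primary tumour labelled with Cy5 and a liver metastasis labelled with Cy3, after amplification with an amino-allyl aRNA kit. The tumours and metastases of the 2 arrays were grown and harvested independently, so each array was counted as 1 biological replicate. The dye orientation was the same on both arrays. A bias of a probe towards 1 dye was therefore part of its ratio on both arrays and could not be removed, and it does not show in the spread between them.

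The deposited table gives 1 value per probe and array, which is a log ratio of the 2 channels and was taken as log2. The log base, the channel in the numerator, the background correction, the spot filter and the normalization are not given in the sources used here. Base 2 was assumed because base 10 would imply ratios beyond the usual range of a scanner, and a natural log was not excluded. Signs are therefore reported as the positive and the negative side of the ratio, without assigning a side to the primary tumour or the metastasis. Over all deposited values the median was 0 on array 1 and -5.53e-06 on array 2, and over the tested probes it was -0.02 and -0.03. The deposited values of array 1 are rounded to hundredths and those of array 2 are not. The table holds no intensities, so no loess fit, background filter or level of a single tissue could be had, and the number of arrays limits the precision.

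Of 23473 probes, 18837 had a value on both arrays, 915 on array 1 only, 1387 on array 2 only and 2334 on neither. Tests used the probes with a value on both. The platform annotation gave 1 gene symbol for 16631 probes, several for 0 and none for 6842. Of the 16631 symbols, 12622 were current in the GRCm38.p6 RefSeq gene table, 3947 were updated through a unique synonym and 62 were kept as given. Examples of updated names are Aes, now Tle5, and Igsf4a, now Cadm1. The genome build behind the probes is not stated, so no coordinates are given. Probes of the same gene were averaged, which gave 13506 genes, 168 of them with more than 1 probe.

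Each probe's ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes), which leaves 1 residual degree of freedom plus a prior of 3.80. P-values were adjusted by Benjamini-Hochberg and 0.05 was the threshold. The same fit on genes gave the values of single genes, and errors are the SD of the 2 arrays. A second count took probes at least 2-fold apart (1 log2 unit) on both arrays. Both counts were repeated with the sign of array 2 turned. Ratios that the arrays share then cancel and widen the spread, so these counts lie below a chance level and are not one. With 2 arrays, turning signs cannot give a two-sided p below 0.5. Figures were drawn with matplotlib 3.10.9.

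Before the data were examined, 34 gene lists were fixed, 16 of cell type markers and 18 of pathways and functions. They hold 530 genes, of which 377 were measured on both arrays. A shift of a list against all other genes was tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the 33 lists that had 2 or more measured genes. Camera with an estimated correlation, rank-based camera and fry were run beside it. With an estimated correlation, camera rests on the 1 residual degree of freedom. Hardly any list could pass it, so its result does not decide whether a list is shifted. With the preset correlation, the p rests on the spread between genes and not on the spread between the 2 arrays. Genes of a list that vary together more than the preset value make that p too small. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The median, the mean and the direction in camera differed in sign for the smooth muscle, B and plasma cell, Notch, TLE and cholangiocyte lists, none of which passed. The rule for named genes, fixed at the same time, took per side the 12 genes with the largest value on their weaker array among genes past the threshold with the same sign on both arrays, leaving out predicted gene models. It added the up to 4 such genes of each list whatever their p, the measured TLE corepressor genes, Notch genes past the threshold over the lists, and Actb, Gapdh and Hprt. Other members of a list that are named were chosen after their values were seen.

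The scripts were tested on simulated ratios for 18837 independent probes. These had the spread between arrays of the real ones and a true ratio of 0, apart from 200 changed probes. True changes of 2, 3 and 4 log2 units were recovered in 80%, 96% and 100% of cases and changes of 1 unit in 2%, with 11 false calls among 150. Among 200 random lists of 18 unshifted genes out of 13506, 4.5% had a camera p under 0.05, and 99% did after a shift of 0.25. The simulated genes were independent and lay closer around 0 than the real ones, so these rates need not hold for the real lists. Scaling set the arrays to equal median absolute values. Alternatives were other centring, scaling and quantile normalization, other moderation and thresholds, probes with 1 value, the level of the test, the probe rule and the array left out. A filter on dim probes could not be run because the values mark none.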

Results

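Gene expression was measured in Colon26 cells, a mouse colon carcinoma line, grown in Balb/c mice. The cells were injected under the lining of the rectum, and RNA was taken from the primary tumours and from the liver metastases that arose from them. The comparison asks which genes differ between the tumour at its first site and its metastases in the liver. Each of 2 arrays compared 1 primary tumour with 1 liver metastasis. A value was present on both arrays for 18837 probes and 13506 named genes, with an SD across the probes of 0.52 on array 1 and 0.56 on array 2. Values are log ratios, taken as log2, and positive and negative values denote the 2 directions of the ratio. Which direction stands for the metastasis is not stated in the sources used here, so no direction is assigned.

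The genes farthest from 0 on the positive side were Ifitm1, an interferon-induced membrane protein, at 4.16 ± 0.42 (SD, n = 2), Akr1c12, an aldo-keto reductase, at 3.97 ± 1.04, and Il2rg, the shared gamma chain of several cytokine receptors, at 3.19 ± 0.42. If the base is 2, the ratio of Ifitm1 was 17.8-fold. They were followed by Enpp2, the secreted enzyme autotaxin, at 2.87 ± 0.90, Abcd2, a peroxisomal transporter, at 2.83 ± 0.80, Dnaaf4 at 2.73 ± 0.82 and Pla2g2a, a secreted phospholipase, at 2.52 ± 0.27. Nr5a1, a nuclear receptor of steroid-producing tissues, had 2.49 ± 0.22. Serpini1, a serine protease inhibitor, had 2.42 ± 0.36, and Gria1, a glutamate receptor subunit, 2.22 ± 0.06. Sema4d and Mllt3 had 2.19 ± 0.28 and 2.12 ± 0.10. All of these passed the threshold in limma's moderated test, with adjusted p from 0.0127 for Ifitm1 to 0.0333 for Enpp2.

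The negative side was led by Cadm1, a cell adhesion molecule, at -4.40 ± 0.37 (SD, n = 2), a ratio of 21.1-fold if the base is 2. Mmp3, the matrix protease stromelysin, had -3.74 ± 0.33. Olfr56, annotated as an olfactory receptor, had -3.68 ± 0.18, and Ces1g, a carboxylesterase, had -3.62 ± 0.03. Tmsb4x, an actin-binding peptide, had -3.38 ± 0.84. Col1a1, a chain of type I collagen, had -2.93 ± 0.18, while Col1a2, the partner chain, had -0.24 ± 0.19 with an adjusted p of 0.365. The others were Cgnl1, a junction protein, at -2.88 ± 0.57, Rgs16, a regulator of G protein signalling, at -2.71 ± 0.17, and Endog, a mitochondrial nuclease, at -2.56 ± 0.06. Tnnt2, cardiac troponin T, Tmem119 and Cytip had -2.49 ± 0.02, -2.27 ± 0.25 and -2.25 ± 0.07. Adjusted p in limma's test ran from 0.0119 for Cadm1, Ces1g and Olfr56 to 0.0282 for Tmsb4x, Cgnl1 and Tmem119. Ces1g, Akr1c12, Tmsb4x and Ppia have close relatives or processed copies in the genome, and their probes may read more than 1 gene.

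**Figure D1:**
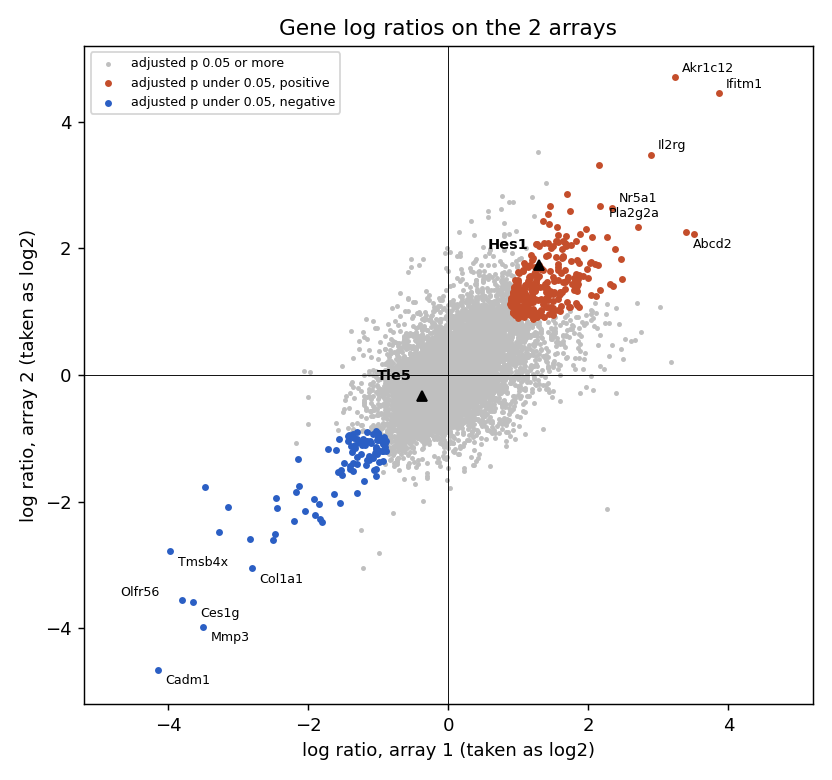
Log ratio of each of 13506 genes on array 1 (x axis) and array 2 (y axis), both taken as log2. Red and blue points are the 286 positive and 105 negative genes with adjusted p under 0.05, and triangles mark Hes1 (1.30 and 1.73) and Tle5 (-0.37 and -0.33).

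In all, 238 of 18837 probes passed an adjusted p of 0.05, 184 on the positive side and 54 on the negative side, and 162 of them carried a gene symbol. The fit on genes, which leaves out probes without a symbol and gives the calls of single genes, gave 391 of 13506, 286 positive and 105 negative. Of the called genes, 157 were also called in the fit on probes. Of the genes named by the rule, Aqp1, Cnn1, Actn3, Cd14, Flt1, Robo4, Tubb3, Aldoa, Cxcl9, Vim and Lama5 were called on genes only. Their adjusted p in limma's test ran from 0.0423 for Cxcl9 to 0.0492 for Robo4. Cd14, Robo4, Vim and Lama5 each stayed called in 1 of 8 alternatives, and Flt1, Tubb3 and Aldoa in 2. Centring on the median was enough to lose Cd14, Robo4, Aldoa, Vim and Lama5. An unadjusted p under 0.05 was met by 5079 probes. A difference of at least 1 log2 unit on both arrays was met by 362 positive and 104 negative probes. With the sign of array 2 turned, 3 probes met that difference and limma called 0, with 54 at an unadjusted p under 0.05, which gives no chance level because the arrays correlate. Across probes, which are not independent replicates, the arrays correlated with Pearson's r of 0.609 and Spearman's rho of 0.577, and 71.8% of probes had the same sign. The smallest adjusted p was 0.0303, and the number of called probes ranged from 0 to 1748 over the alternatives. Of 39 called genes named here, 17 passed after scaling the arrays to equal spread and 4 after quantile normalization (Cadm1, Ces1g, Ifitm1 and Olfr56).

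Genes of glycolysis and the response to low oxygen lay together on the negative side. Of 18 measured members, 15 were negative on both arrays, 3 had mixed signs and 0 were positive on both. The median was -0.75, with -0.88 on array 1 and -0.52 on array 2. Pgk1, phosphoglycerate kinase, at -1.37 ± 0.02 (SD, n = 2) and Aldoa, an aldolase, at -1.03 ± 0.18 passed the threshold over all genes. Pgk1 stayed called in 5 of 8 alternatives and Aldoa in 2. Adjusted over the list alone, 11 members passed. These 11 also included Pdk1, a kinase that inhibits pyruvate dehydrogenase, at -1.39 ± 0.87, and Ldha, lactate dehydrogenase, at -1.06 ± 0.25. Among them were also Slc2a1, a glucose transporter, at -0.93 ± 0.19, and Pgam1, phosphoglycerate mutase, at -0.91 ± 0.07. Ddit4, a stress-induced regulator of growth, at -0.91 ± 0.26, and Ndrg1 at -0.78 ± 0.13 belonged to them as well. The hypoxia targets Vegfa and Car9 had -0.12 ± 0.16 and -0.40 ± 0.19 and did not pass. Against all other genes the list was shifted in limma's camera (adjusted p = 3.15e-06 with the preset correlation, adjusted p = 0.988 and unadjusted p = 0.153 with an estimated correlation). The version with an estimated correlation has 1 residual degree of freedom and hardly any power. The version with the preset correlation rests on the spread between genes and not between arrays, so its p can be too small. Fry gave an adjusted p of 0.285.

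Several genes often used as references also lay on the negative side. Ppia, cyclophilin A, had -1.52 ± 0.02 (SD, n = 2) and passed, with an adjusted p of 0.0283 in limma's test, as did Pgk1, which is on both lists. Actb had -0.63 ± 0.11, Gusb -0.49 ± 0.02, Hprt -0.37 ± 0.01 and Gapdh -0.31 ± 0.12, none past the threshold over all genes. Tbp and Sdha were positive on both arrays, at 0.16 ± 0.14 and 0.09 ± 0.09. Of the 11 measured housekeeping genes, 7 were negative and 2 positive on both arrays, 2 passed over all genes and 3 adjusted over the list alone, and the shift of the list missed the threshold (camera adjusted p = 0.0805). The median of the list was -0.37, and it was -0.34, -0.37 and -0.37 after centring, scaling and quantile normalization. These settings moved the median by little, so its kept sign does not test a shift tied to dye or intensity. Genes of oxidative phosphorylation had a median of -0.10 over 20 members, of which 11 were negative on both arrays, 4 positive on both and 5 of mixed sign. The members farthest from 0 on their weaker array were Atp5b at -0.83 ± 0.20, Cyc1 at -0.51 ± 0.36, Ndufb8 at -0.40 ± 0.17 and Cox5b at -0.39 ± 0.08. Limma called 0 of the 20, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.509).

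**Figure D2:**
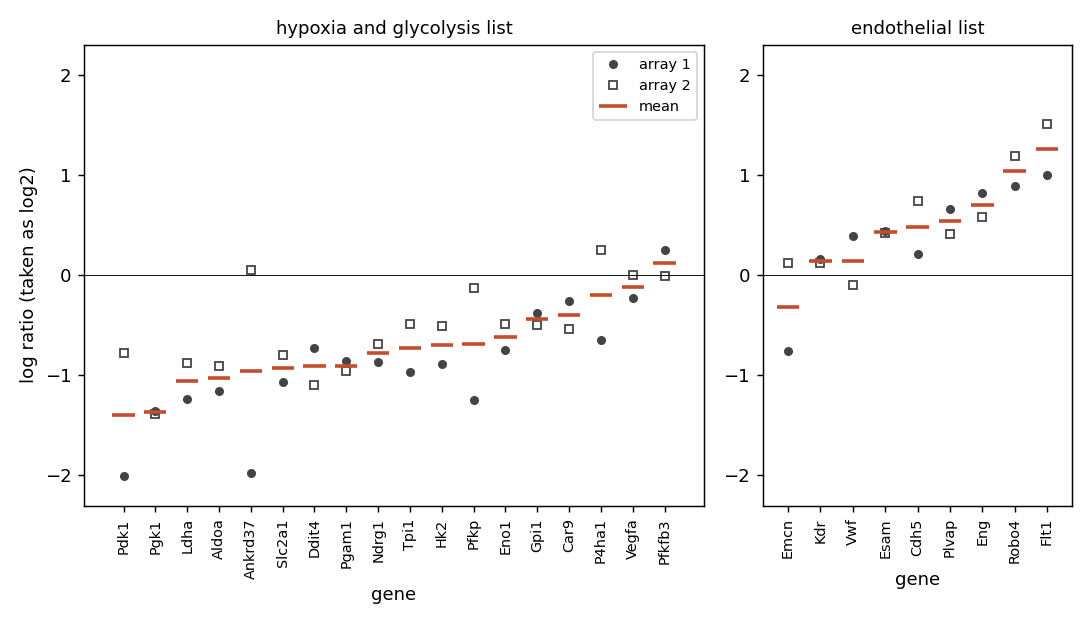
Log ratio, taken as log2, of each measured gene of the hypoxia and glycolysis list (left, 18 genes) and the endothelial list (right, 9 genes). Filled circles are array 1, open squares array 2 and bars their mean; Pgk1 lies at -1.36 and -1.38 and Flt1 at 1.00 and 1.51.

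Endothelial genes lay on the positive side. Of 9 measured, 7 were positive on both arrays, 2 had mixed signs and 0 were negative on both, with a median of 0.48. Flt1, a receptor for vascular endothelial growth factors, at 1.25 ± 0.36 (SD, n = 2) and Robo4 at 1.04 ± 0.21 passed over all genes. Their adjusted p in limma's fit on genes, 0.0475 and 0.0492, lay near the threshold, and neither passed in the fit on probes. Flt1 stayed called in 2 and Robo4 in 1 of 8 alternatives. Together with Eng (0.70 ± 0.17) and Plvap (0.54 ± 0.18) they made 4 that passed adjusted over the list alone. Esam had 0.43 ± 0.02, Cdh5 0.48 ± 0.38 and Kdr 0.14 ± 0.03. Camera gave an adjusted p of 0.0331 with the preset correlation, and with an estimated correlation an adjusted p of 0.988 and an unadjusted p of 0.192. The latter version has 1 residual degree of freedom and hardly any power, and the former rests on the spread between genes and not between arrays. Rank-based camera gave an adjusted p of 0.0537 and fry 0.224. Of the 13 genes in the list, 2 more had a value on 1 array only. A dye bias or an effect of dim probes was not tested for this list and cannot be told apart. Genes of the liver sinusoidal endothelium had a median of 0.00 over 4 members, with Fcgr2b at 0.91 ± 0.61 and Lyve1 at -0.22 ± 0.22, and limma called 0 of 4 (1 with an unadjusted p under 0.05).

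Hepatocyte genes showed no common side. Among 18 measured, 3 were positive on both arrays, 6 negative on both and 9 of mixed sign, and the median was -0.02, which turned positive after centring, scaling or quantile normalization (camera adjusted p = 0.980). Ttr, transthyretin, had 0.80 ± 0.06 (SD, n = 2), Trf, transferrin, 0.68 ± 0.44, Fah, an enzyme of tyrosine breakdown, -0.95 ± 0.50, and Apoc3 -0.51 ± 0.07. Alb, albumin, had -0.34 ± 0.43. Limma called 0 of the 18, and 5 had an unadjusted p under 0.05. Acute phase genes (9 measured, median -0.20), Kupffer cell markers (4, median 0.01) and cholangiocyte markers (7, median 0.14) were likewise not shifted, with camera adjusted p of 0.870, 0.961 and 0.984. Clec4f, a Kupffer cell lectin, had 0.31 ± 0.02, Socs3 -0.42 ± 0.04 and Saa2 -0.39 ± 0.27. The acute phase genes Lbp and Lcn2 had 0.53 ± 0.48 and -0.27 ± 0.21. Limma called 0 acute phase and 0 Kupffer cell genes, with 1 and 0 at an unadjusted p under 0.05. Aqp1, a water channel listed for bile duct cells and also made by other cells, was the 1 called cholangiocyte gene at -1.10 ± 0.10, with Epcam at 0.34 ± 0.39, Sox9 at -0.26 ± 0.04 and Cftr at 0.14 ± 0.11.

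Markers of the tissues around the rectal tumour were mixed. Of 15 colonic epithelium genes, 6 were positive and 5 negative on both arrays and limma called 0, with 4 at an unadjusted p under 0.05. Examples are Slc9a3 at 0.66 ± 0.03 (SD, n = 2), Vil1 at -0.42 ± 0.17 and Lgals4 at -0.36 ± 0.05. The 2 probes of Krt20 disagreed, with means of 1.25 and -0.27. Among 9 smooth muscle genes, Cnn1, calponin, was called at 1.15 ± 0.24. Des, desmin, at 0.89 ± 0.16, Actg2 at -0.65 ± 0.01 and Smtn at -0.55 ± 0.02 passed adjusted over the list alone, in opposite directions. In skeletal muscle, Actn3 was called at 1.27 ± 0.28, and Tnnc2, Myl1 and Mylpf had 0.63 ± 0.26, 0.53 ± 0.39 and 0.26 ± 0.27. Tubb3, listed for neurons, was called at -1.07 ± 0.18, while Sox10 had 0.43 ± 0.13 and Uchl1 0.11 ± 0.11. None of these lists was shifted: camera adjusted p was 0.870 for colonic epithelium, 0.961 for smooth muscle, 0.228 for skeletal muscle and 0.870 for enteric neurons and glia. Adipocyte markers (5 measured, camera adjusted p = 0.870) and erythroid markers (2 measured, 0.885) held 0 called genes in limma's test. Fabp4 had 0.56 ± 0.39, Plin1 -0.46 ± 0.44, Retn -0.29 ± 0.38 and Epb42 -0.28 ± 0.03, and 1 and 0 genes of these lists had an unadjusted p under 0.05.

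**Figure D3:**
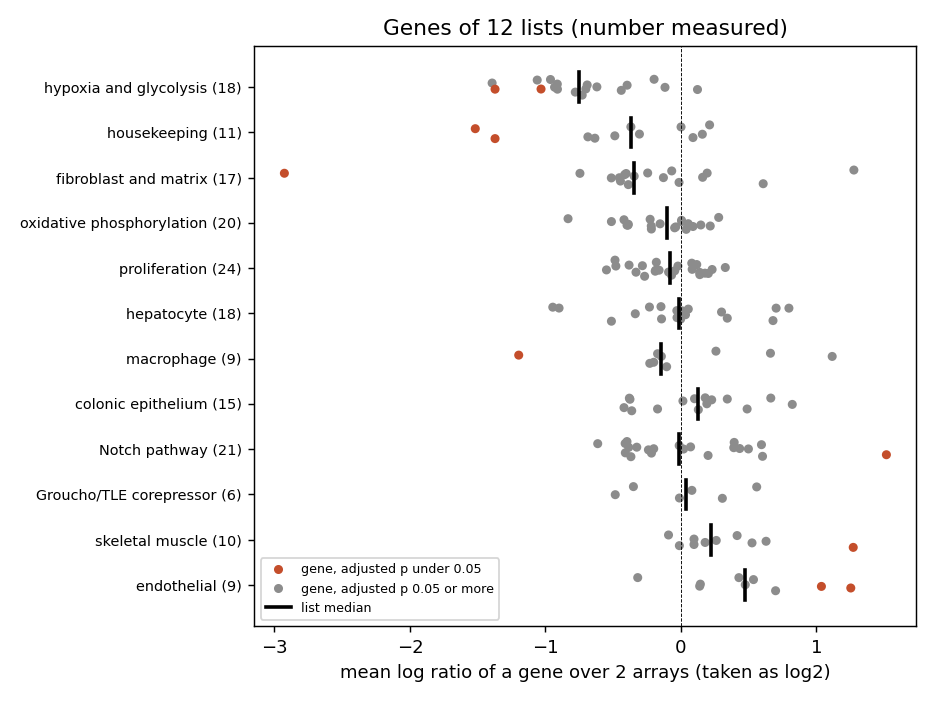
Mean log ratio over 2 arrays (x axis, taken as log2) of each measured gene in 12 of the 34 lists, with the number measured in brackets. Red points have an adjusted p under 0.05, grey points do not, and bars are list medians, from -0.75 for hypoxia and glycolysis to 0.48 for the endothelial list.

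Immune cell markers gave a call in 1 list. Of 9 macrophage genes, Cd14, the co-receptor for bacterial lipopolysaccharide, was called at -1.20 ± 0.33 (SD, n = 2). Its call was kept in 1 of 8 alternatives and lost after centring (limma adjusted p = 0.0512). Fcgr1, an Fc receptor, had 1.12 ± 0.52 and passed adjusted over the list alone, and Cd163 and Cd68 had 0.66 ± 0.38 and -0.20 ± 0.01. The neutrophil list divided, with S100a8 at -0.88 ± 0.26 against Mpo at 0.97 ± 0.31 and Mmp9 at 1.08 ± 0.80, all past the threshold over the list alone, and Ly6g had 0.37 ± 0.16. Cd2 and Cd5, surface proteins of T cells, had 0.99 ± 0.24 and 0.97 ± 0.41 and passed over the list alone, whereas Cd4 and Cd8a had -0.16 ± 0.19 and -0.04 ± 0.13. Ifng, interferon gamma, had 0.62 ± 0.29 and Gzmb, granzyme B, -0.08 ± 0.05. In the B and plasma cell list Cd79b had 0.91 ± 0.51, Ms4a1 0.51 ± 0.07, Cd79a -0.29 ± 0.07 and Ighm -0.41 ± 0.25. Limma called 0 genes of the neutrophil, T and NK cell and B and plasma cell lists over all genes, with 3, 3 and 2 at an unadjusted p under 0.05. Camera adjusted p was 0.961 for macrophages, 0.870 for neutrophils, 0.510 for T and NK cells and 0.961 for B and plasma cells.

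The interferon response list was not shifted (camera adjusted p = 0.870, 17 genes), although Cxcl9, a chemokine induced by interferon gamma, was called at 1.88 ± 0.61 (SD, n = 2). Bst2 had -0.73 ± 0.14 and passed over the list alone, Psmb9 had 0.88 ± 0.55 and Rsad2 -0.53 ± 0.04. Cxcl9 was also the 1 called gene among 18 chemokines and receptors (camera adjusted p = 0.735), where Cx3cl1 had -0.71 ± 0.31, Ccl3 0.44 ± 0.04 and Ccl4 0.91 ± 0.74. Of the genes of MHC class II, 3 were measured, H2-Aa at -0.30 ± 0.08, Ciita at -0.26 ± 0.05 and Cd74 at 0.23 ± 0.08, and limma called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.870).

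Notch signalling was examined because the corepressor Aes, now named Tle5, and the Notch pathway have been studied in metastasis of colon cancer. Hes1, a transcription factor induced by Notch, was called at 1.52 ± 0.31 (SD, n = 2; limma adjusted p = 0.0365), a ratio of 2.86-fold if the base is 2. It was the 1 gene past the threshold over the Notch and TLE lists alone. Notch2 had 0.60 ± 0.04, Rbpj, the DNA-binding partner of Notch, -0.61 ± 0.11, and Notch4 -0.41 ± 0.05. The other Hes and Hey genes measured in the list were Hes5 at -0.40 ± 0.09 and Hey1 at 0.50 ± 0.54. Of 21 Notch pathway genes, 8 were positive and 8 negative on both arrays (camera adjusted p = 0.984). Tle5 was negative on both arrays, at -0.35 ± 0.03, with a 95% limma interval from -0.74 to 0.03 and an adjusted p of 0.208. Tle4 had -0.48 ± 0.08, Tle6 0.56 ± 0.47, Tle1 0.31 ± 0.38, Tle2 0.08 ± 0.10 and Tle3 -0.01 ± 0.17. Limma called 0 of the 6 TLE genes, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.984). Over all genes the call of Hes1 was lost in 4 of 8 alternatives, with an adjusted p in limma of 0.0518 after scaling to equal spread, 0.0564 after quantile normalization, 0.0538 with a minimum fold of 1.2 and 0.472 without moderation, and the lowest of the 8 was 0.0371. Over the Notch and TLE lists alone it passed in each alternative except without moderation (limma fit, adjusted p = 0.334), where 1 residual degree of freedom leaves hardly any power.

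Genes of matrix, invasion and adhesion held some of the widest ratios without a common side. In the fibroblast and matrix list, 10 of 17 genes were negative and 2 positive on both arrays, and Col1a1 alone was called. Sparc had -0.74 ± 0.01 (SD, n = 2), against Bgn, biglycan, at 1.28 ± 0.71 and Fbn1 at 0.61 ± 0.03. Among 18 extracellular protease genes Mmp3 was called. Plat, tissue plasminogen activator, had 1.14 ± 0.39, Mmp13 -0.84 ± 0.04 and Mmp9 1.08 ± 0.80, and 4 positive and 3 negative genes passed over the list alone. Lama5, a laminin chain, was the 1 called member of the adhesion list at -0.97 ± 0.07, with Lamc1 at -0.88 ± 0.08, Sdc4 at -0.81 ± 0.10 and Itgb4 at 1.73 ± 0.94. Vim, vimentin, was the 1 called gene of the epithelial-mesenchymal list at -1.02 ± 0.17. The calls of Lama5 and Vim were each kept in 1 of 8 alternatives and lost after centring (limma adjusted p = 0.0523 and 0.0521). S100a4 and Cldn7 had -0.65 ± 0.13 and -0.49 ± 0.33, and Tjp1 had 0.48 ± 0.19. Camera adjusted p was 0.228 for fibroblast and matrix, 0.870 for proteases, 0.539 for adhesion and 0.834 for the epithelial-mesenchymal list.

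In the TGF-beta and BMP list Ccn2, connective tissue growth factor, was called at 1.41 ± 0.14 (SD, n = 2), with Bmp7 at 0.73 ± 0.20, Tgfb1 at 0.50 ± 0.10 and Tgfb2 at -0.63 ± 0.25 (camera adjusted p = 0.539 over 16 genes). Targets of Wnt signalling included Znrf3 at 0.81 ± 0.15, Ephb3 at -0.50 ± 0.27, Ascl2 at -0.42 ± 0.16 and Myc at -0.35 ± 0.06, with 0 of 13 called by limma and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.735). Of the metastasis suppressor list, Ndrg1, Nme1 (-0.75 ± 0.23) and Nme2 (-0.57 ± 0.02) passed over the list alone, 0 of 11 were called over all genes with 4 at an unadjusted p under 0.05, and Cd82 had 0.59 ± 0.29 (camera adjusted p = 0.228). Proliferation genes lay close to 0, with a median of -0.08 over 24 genes, Bub1b at -0.55 ± 0.15, Plk1 at -0.49 ± 0.25, Birc5 at -0.38 ± 0.04 and Top2a at -0.33 ± 0.03. Limma called 0 of them, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.735). Immediate early and heat shock genes had a median of -0.02 over 12 genes, which turned positive after centring, with Dusp1 at 0.51 ± 0.02, Fos at 0.54 ± 0.33, Junb at -0.37 ± 0.02 and Nr4a1 at -0.30 ± 0.16. Limma called 0 of these, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.980). Of the sex-linked list only Kdm5d was measured on both arrays, at -0.20 ± 0.07.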

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

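The tests of dim spots, receptor genes and centring as a cause were chosen after the result had been seen, while the counts under other settings had been planned. Probes with a value on 1 array only, which were left out of the tests except in 1 alternative, lay far on the positive side. Their median was 0.83 over 2302 probes, 0.95 for those on array 1 only and 0.75 for those on array 2 only, and 85.7% were above 0, against 47.5% of the probes with a value on both arrays. Called probes leaned the same way, with 77.3% on the positive side, but 38 of 60 were positive after scaling, 1 of 4 after quantile normalization and 1 of 6 with a minimum fold of 1.2.

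Centring of the deposited values cannot be told apart as a cause of that lean: centring the tested probes on their own median left 79.4% of the calls positive, but their medians lay below 0, so this could move values to the positive side only. Dim spots whose denominator channel lies near background stay open as a contribution. Few tissues express olfactory and vomeronasal receptor genes, and their 147 probes with a value on 1 array had a positive median of 0.72 (95% bootstrap interval 0.57 to 0.87). The 2155 other probes with a value on 1 array had a median of 0.84. Receptor probes thus did not stand out among them, and their median cannot decide the question. Such receptor probes lacked a value on 1 or both arrays in 40.7% of cases against 19.1% of other probes. How far dim spots reach into the calls stays open: receptor probes made up 3.80% of the positive calls and 2.34% of the tested probes (two-sided Fisher exact p = 0.209), receptor genes 5.24% of the positive calls and 3.26% of the tested genes in the fit on genes (15 positive and 3 negative calls; two-sided Fisher exact p = 0.0628), and the 440 receptor probes with a value on both arrays had a median of -0.01. A difference between the primary tumours and the metastases stays open and was not tested.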

How the results depend on the processing

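The number of called probes moved most. Against 238, it was 60 after scaling to equal spread, 4 after quantile normalization, 6 with a minimum fold of 1.2, 391 on genes, 366 on probes with 1 gene symbol, 984 with values on 1 array kept (315 of them on such probes) and 1748 at an adjusted p under 0.1. Without moderation limma's fit called 0, with 2019 at an unadjusted p under 0.05 and a smallest adjusted p of 0.449. That fit rests on 1 residual degree of freedom, so hardly any ratio could pass after adjustment. Fewer tests, a looser threshold, added probes and the loss of prior degrees of freedom are part of how some of these settings are built. For the others the cause was not tested. Against 184 of 238 on the positive side, 38 of 60 were positive after scaling, 1 of 4 after quantile normalization and 1 of 6 with the minimum fold. Centring (355) and robust moderation (214) stayed within 1.5 times of the count. The count by fold, 466, was 1775 at 1.5-fold, 93 at 3-fold, 306 on genes, which are fewer than the probes, and 1120 to 1343 on 1 array alone. The correlation was 0.577 without the 1% of widest probes. The 2 shifted lists became 0 with an estimated correlation, 0 with fry and 1 with rank-based camera, and both stayed after centring, scaling and with 1 probe per gene. With an estimated correlation camera has 1 residual degree of freedom, so hardly any list could pass and the 0 does not decide. With the preset correlation its p rests on the spread between genes and not between arrays, so the 2 shifts are not settled by it either. Of the Notch and TLE genes, 1, Hes1, passed over those lists in each of the 4 alternatives planned for them, and 0 did without moderation (2 at an unadjusted p under 0.05). The 39 called named genes kept their sign in 8 alternatives. These settings leave the mean as it is or move it by little, so a kept sign is no support for a call. Of the 39, 34 stayed called after centring, 31 with robust moderation, 32 with 1 probe per gene and 26 with the minimum fold. Without moderation 0 stayed called, and 39 did with values on 1 array kept. With 1 array left out no degrees of freedom remain, so the count of calls and the list tests have no such value. A filter on dim probes was not run, because the values mark none. No separate paired analysis was run, because each array already holds both tissues in 1 ratio. The test of that ratio against 0 uses this pairing. Simulated changes of 1 log2 unit were recovered in 2% of cases. The simulated ratios lay closer around 0 than the real ones, so that rate need not hold for the real data. In the fit on probes, the smallest absolute mean among called probes was 1.22. The fit on genes called Lama5 at -0.97, Vim at -1.02 and Robo4 at 1.04, but not Ldha at -1.06 or Plat at 1.14. Differences of about 1 unit could therefore be missed with 2 arrays, and how often was not tested on the real data.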

Other observations

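Apart from the test of dim spots on chromosome 3, the tests in this part were chosen after the result had been seen. Ribosomal protein genes, which no list covered, lay on the negative side, with 49 of 66 negative on both arrays, 11 positive on both and a median of -0.40 (95% bootstrap interval -0.59 to -0.30). Limma called 4 of them, all negative. Their median was -0.37, -0.40 and -0.40 after centring, scaling and quantile normalization, which moved it by little and do not test a shift tied to dye or intensity. Camera gave p = 3.19e-08 with the preset correlation and p = 0.172 with an estimated correlation, where it has 1 residual degree of freedom and hardly any power. The smaller p rests on the spread between genes and not between arrays. The 32 collagen genes had a median of -0.22 (-0.36 to 0.01), the 45 translation initiation factors -0.11 (-0.19 to 0.06) and the 37 proteasome subunits -0.05 (-0.19 to 0.16).

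Genes of hypoxia and glycolysis lay on the negative side with a median of -0.75. A shift of abundant transcripts, to which glycolytic enzymes belong, cannot be told apart. The median of the list minus that of the ribosomal protein genes was -0.35 (95% bootstrap interval -0.59 to -0.09). Minus that of 10 other abundant transcripts, among them Tmsb4x, Fth1, Ppia and Eef1a1, which limma called negative, it was -0.0671 (-0.515 to 0.862). These 10 were listed after some of their values had been seen, so that comparison cannot decide, and abundance itself was not measured. Probes shared with pseudogenes of the enzymes argue poorly as the whole cause. The 9 members that are not glycolytic enzymes had a median of -0.78 (-0.96 to -0.12), next to -0.73 (-1.06 to -0.62) for the 9 enzymes. The enzymes were the more uniform part, with 9 of 9 negative on both arrays against 6 of 9 other members, so a contribution of such probes stays open. A dye bias common to these probes stays open, as the dyes were not swapped. A difference in oxygen or glucose supply between the sites is a hypothesis that was not tested, and the unstated direction of the ratio leaves open which site it would concern.

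On chromosome 3, the 25 neighbouring measured genes from Gmps to Golim4 had a median of 0.58 (95% bootstrap interval 0.25 to 1.03), with 22 positive on both arrays and 8 called in the fit on genes, among them Serpini1 at 2.42 ± 0.36, Tiparp at 1.45 ± 0.20 and Rarres1 at 1.35 ± 0.37. The window was picked for the largest absolute median among 12747 windows, which widens these values. A chance order of genes is unlikely as the cause: 2 of 1000 shuffled orders held a 25-gene window with a median as large, and by the statistic tried first, the mean of 15 neighbours (0.71 from Lxn to Golim4), 24 of 1000 did. Neighbouring genes correlated over all ordered genes (Spearman's rho 0.0772, highest over shuffled orders 0.0282), so the shuffles do not single out this window. Gene-poor regions in general cannot be told apart. The 778 other windows of at least the same span had a median of 0.083 (0.056 to 0.101 over resampled chromosomes). A lower median of other windows follows in large part from picking the widest window, so it does not decide. The highest of them, 0.39, lies within the interval of this window, and span and median correlated across overlapping windows (Spearman's rho 0.469). Dim spots cannot be told apart, since 24.2% of the 33 probes in the window lacked a value on 1 or both arrays against 17.7% elsewhere (one-sided Fisher exact p = 0.219). A difference in copy number between the tumour cells of the sites was not tested, and neither was base composition.

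Runs of 25 genes on chromosome 5, from Ptpn13 to Gfi1, and on chromosome 14, from Lcp1 to Wbp4, had medians of 0.58 and 0.51, and 2 and 11 of 1000 shuffled orders held a window as large. On the single arrays the run on chromosome 14 had medians of 0.35 and 0.36. A run on chromosome 2, from Gpsm1 to Dbh, had -0.45, with 68 of 1000. These runs were picked from the same windows for their large medians. Neighbouring genes correlate in general, so the shuffles do not single them out, and their causes were not tested.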
